A study of Homo sapiens with 4 samples.

How the data were processed

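Ribosome footprints and randomly fragmented total RNA from 2 SW480-derived lines were measured in 4 libraries, 1 per line and assay. Per the labels' protocols, footprints of 18 to 34 nt and RNA fragments of 18 to 50 nt were selected, linkers carried random identifiers of 4 nt at the 5' end and 5 nt at the 3' end, ribosomal RNA was depleted, and cDNA was amplified over 15 PCR cycles. The deposited values are whole-number counts per gene, with 1 transcript listed for each of 19192 genes, per the file headers and the values. Per the submitters' processing notes, cutadapt 1.10, Bowtie 1.1.2, HISAT2 2.1.0 and the build GRCh38 were used; the notes give no role or order. The counter, the annotation release, the counted part of the transcript and any use of the random identifiers to collapse duplicates are not given in the sources used here. If PCR copies were counted, intervals and floors, which cover counting error only, are too narrow. Per the labels, 1 library's cell line field reads SW840 while its source field reads SW480; it was taken as SW480.

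Samples were grouped by their genotype label and assay. As IGF2BP1 was higher in the libraries labelled as its knockout, groups are called OE-labelled and knockout-labelled throughout. Counts were scaled within each assay with TMM factors from edgeR 4.0.16 (R 4.3.3). A gene entered a comparison with a mean count of at least 50 over the 2 libraries of the assay, or of each assay for translational efficiency. The log2 ratio was taken with 0.5 added to each count, and its 95% interval is the exact conditional binomial (Clopper-Pearson) interval of the 2 counts. The translational efficiency ratio is the footprint ratio over the mRNA ratio, with a Wald interval from the 4 counts. A model with an interaction term needs replicates and was not fitted, and no p-value was computed. A count of 0 was set to a floor of 3 counts per library to give a fold. The floor is 0.553 and 0.440 CPM in the OE-labelled and knockout-labelled RNA libraries and 1.10 and 0.920 in the footprint libraries. The 95% interval can reach nearer to 0 than such a fold.

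Before the data were examined, 39 gene lists, the fold threshold of 2, the filters, the rule for named genes and the scalings of gene counts and single genes were fixed. For list medians, upper-quartile scaling and total counts without mitochondrially encoded genes were added after the data were seen. List members were counted at 1.5-fold, and lists with at least 5 measured members were given a median, an order-statistic 95% interval over members, and a percentile among 10000 random lists drawn from 20 bins of mean count. Of the lists, 35 reached 5 measured members in mRNA and 34 in translational efficiency. Named genes are IGF2BP1, LIN28B and their paralogues; the 12 highest and 12 lowest genes of each ratio, ranked by the interval bound nearest to 0; the 12 highest and 12 lowest by the smaller of both assays' bounds; 2 to 4 members per list with the highest counts among those at least 1.5-fold different in the direction of its median, or among all members where none was; and the measured WNT and IMP1 target lists. Some genes named by the rule are not reported here. Markers of other cell types and members in the direction opposite to a median are named outside the rule, after their values were seen. Coordinates and coding lengths are those of the listed transcript in GENCODE release 29 (GRCh38), in which 19176 of 19192 transcript identifiers were found.

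The ratio, interval and list steps were tested on simulated counts drawn from the real genes' shares and library totals, with 200 genes changed by 2-fold or 4-fold. The draws were Poisson, without variation between libraries, and were scaled by the median ratio in place of TMM. They check the steps under counting error only, the error that the intervals assume. In the RNA simulation (9822 genes), 100% of 96 genes changed 4-fold and 60.2% of 98 genes changed 2-fold were at or past 2-fold, and 95.4% of intervals held the true value. In the footprint simulation (7302 genes) these were 100% of 88, 52.7% of 93 and 95.9%, and in the efficiency simulation (7234 genes) 100% of 84, 47.9% of 96 and 95.3%. The alternatives were DESeq2 1.42.0 size factors, total counts with and without mitochondrially encoded genes, upper-quartile scaling, count minimums of 10, 200 or none, fold thresholds of 1.5 and 3, and 5 added to each count. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.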

Results

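Ribosome footprints and matched RNA fragments were sequenced from 2 derivatives of SW480, an established human colorectal adenocarcinoma cell line. One line was labelled as overexpressing LIN28B (OE), an RNA-binding protein that blocks the maturation of let-7 microRNAs. The other was labelled as overexpressing LIN28B and carrying a knockout of IMP1, the RNA-binding protein encoded by IGF2BP1 that affects the stability, localisation and translation of its target mRNAs. Each line gave 1 RNA-seq library and 1 footprint library, and each library came from 3 pooled culture plates. The comparison addresses which mRNAs differ in abundance and in ribosome occupancy between the lines. Total counts over 19192 genes were 5429224 (OE-labelled RNA), 6813372 (knockout-labelled RNA), 2732760 (OE-labelled footprints) and 3260262 (knockout-labelled footprints). With 1 library per line and assay, no difference below has a replicate check. All ratios are the knockout-labelled over the OE-labelled library, and 95% intervals cover counting error only.

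The targeted gene was not lower in the libraries labelled as its knockout. IGF2BP1 (transcript ENST00000290341, chromosome 17, 48997412 to 49055650, GRCh38) was 1.73-fold higher in the knockout-labelled RNA library (840 against 1974 counts; log2 ratio 0.79, 95% interval 0.67 to 0.91). Its footprints were 2.04-fold higher there (332 against 821 counts; log2 ratio 1.03, 0.84 to 1.22). LIN28B (ENST00000345080, chromosome 6, 104957048 to 105083332), overexpressed in both lines per the labels, was 5.41-fold lower in mRNA (1205 against 303 counts; log2 ratio -2.43, -2.62 to -2.25) and 4.96-fold lower in footprints (190 against 46 counts; log2 ratio -2.31, -2.82 to -1.85). The counts do not separate reads of a LIN28B transgene from those of the endogenous gene. Of the IMP1 paralogues, IGF2BP3 mRNA was 2.01-fold lower (382 against 259 counts) and its footprints 1.20-fold lower, while IGF2BP2 had log2 ratios of 0.08 in mRNA and 0.42 in footprints. LIN28A had 0 and 7 RNA counts and no footprint count. Every direction below is therefore between libraries carrying these labels, which also differ in LIN28B, and not a measured loss of IMP1.

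**Figure D1:**
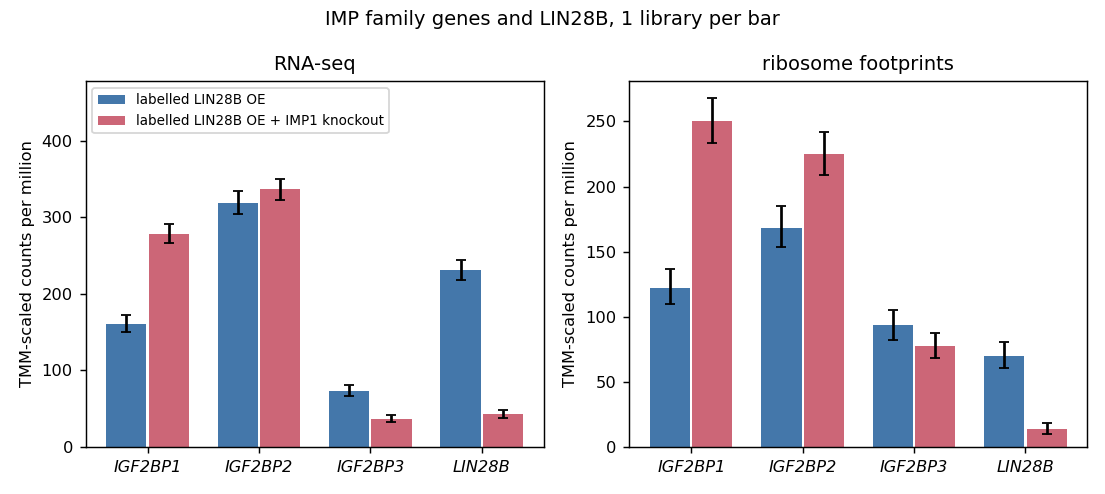
TMM-scaled counts (CPM) of IGF2BP1, IGF2BP2, IGF2BP3 and LIN28B in the RNA-seq (left) and footprint (right) libraries, 1 library per bar, with exact Poisson 95% intervals of the counts. IGF2BP1 stands at 161 in the OE-labelled and 278 in the knockout-labelled RNA library, and LIN28B at 231 and 42.7.

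In mRNA, 295 of 9855 genes were at least 2-fold higher and 344 at least 2-fold lower in the knockout-labelled library. Among the genes furthest above 0 were FLNC, which encodes the actin cross-linker filamin C (5.71-fold higher, 329 against 2562 counts), the dipeptidase gene DPEP1 (8.22-fold) and AREG, which encodes the EGF receptor ligand amphiregulin (7.02-fold). CATSPERB, a subunit gene of a sperm calcium channel, had 9 and 315 counts (24.4-fold). VGLL3, a cofactor of TEAD transcription factors, was 8.02-fold higher, BHLHA9 7.38-fold, the cytokine gene TNFSF15 6.42-fold and HCFC2 5.95-fold. The MAP kinase phosphatase gene DUSP1 was 4.46-fold higher, the arrestin-domain gene ARRDC4 4.36-fold and the bradykinin receptor gene BDKRB2 4.33-fold. IGHE stood 20.6-fold higher, which is uncertain because immunoglobulin constant genes have near-identical copies.

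The genes furthest below 0 in mRNA were led by IGFBP3, which encodes an IGF-binding protein (272 against 6 counts, 57.1-fold lower; log2 ratio -5.83, -7.41 to -4.81), and ASB4 (163 against 4 counts, 49.5-fold lower). TNFRSF6B, a decoy receptor gene, had 110 and 3 counts (log2 ratio -5.43, -7.94 to -4.06). IQGAP2, a scaffold protein gene, was 19.2-fold lower, ISM1 16.6-fold, the glutamate transporter gene SLC1A2 14.3-fold, the growth factor gene FGF3 12.1-fold and BCL2L15 10.7-fold. EPAS1, which encodes the hypoxia-inducible factor HIF-2alpha, was 8.12-fold lower (1846 against 309 counts), CLSTN2 6.47-fold and the matrix protein gene TGFBI 5.88-fold (1302 against 301 counts). SAA1 was 9.49-fold lower, and its reads cannot be separated with certainty from those of SAA2. If both libraries held each gene at the same share, counting noise alone would put 0.29 genes past 2-fold. Scaling by total counts moved the median of all genes from 0.01 to 0.13 and the split from 295 higher and 344 lower to 408 and 261 (406 and 262 with mitochondrially encoded genes left out of the totals).

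Gene lists are described here by their median log2 ratio and its percentile among 10000 random lists of equal size matched on mean count, as a description of these libraries. Members named beside a median were mostly picked in its direction, so they do not show the spread of the list. Genes described as WNT and beta-catenin targets were lower in the knockout-labelled RNA library, with a median of -0.45 (-1.08 to 0.03; 32 measured) that lay below every random list. 15 were at least 1.5-fold lower and 5 at least 1.5-fold higher. In settings chosen after the data were seen, the median was -0.29 once the median of each member's 40 nearest genes was subtracted, and -0.14 without the 5 lowest members. AXIN2, a negative feedback regulator of the pathway, had a log2 ratio of -1.69 (-1.88 to -1.51). The cell cycle gene CCND1 stood at -1.53 (6846 against 3216 counts), CD44 at -1.51, the transcription factor genes SP5 at -1.48 and SOX9 at -1.15, WNT6 at -1.64, RNF43, whose product removes WNT receptors, at -1.32 and APCDD1 at -2.34. PPARD (-1.20), ASCL2 (-1.08), NOTUM (-0.89), TIAM1 (-0.76), PROX1 (-0.73), ETS2 (-0.66), TCF7 (-0.64) and LEF1 (-0.48) were also lower. TIAM1 and ETS2 lie on chromosome 21, whose genes had a median of -0.53. In the opposite direction were CCDC80 (1.90), JUN (1.33), DKK1 (1.18), VEGFA (1.14) and FOSL1 (0.84). EPHB2 (-0.01), BMP4 (0.03), PORCN (-0.07), FZD7 (0.09), KREMEN1 (-0.14), ZNRF3 (0.15), BIRC5 (0.15), PLAUR (-0.17), SLC12A2 (0.39) and EPHB3 (-0.42) stood nearer to 0. Intestinal stem cell markers had a median of -0.69 (-1.32 to 0.11, 14 measured, 8 at least 1.5-fold lower, 0 higher), also below every random list. Most of the measured markers are in the WNT list, among them AXIN2, CD44, RNF43, SOX9, ASCL2 and ETS2. The medians of these lists are therefore not separate results. WNT pathway components had a median of 0.13 (percentile 88.2).

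Genes of the p53 response were higher in mRNA, with a median of 0.33 (0.11 to 0.58; 23 measured; percentile 99.8). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, stood at 0.59, GADD45A at 1.00, GDF15 at 1.23 and SESN2 at 0.74. Of the 23, 6 were at least 1.5-fold higher and 2 at least 1.5-fold lower, BBC3 (-0.64) and FAS (-0.59). ATF4 and amino acid stress genes had a median of 0.23 (percentile 99.9), with DDIT3 at 0.94 and the amino acid transporter gene SLC3A2 at 0.63. Unfolded protein response genes and chaperones of the endoplasmic reticulum had a median of 0.27 (percentile 99.8), with HSPA5 at 1.02, SEC24D at 1.27 and XBP1 at 0.72. Mitotic genes had a median of 0.17 with an interval across 0 (-0.07 to 0.30; percentile 98.7). Of 50 measured, 6 were at least 1.5-fold higher, among them CDK1 (0.70), AURKB (0.71) and TPX2 (0.68), and CDC25B (-0.88) was lower. Lower lists included the cytosolic ribosomal proteins (median -0.30, -0.35 to -0.28; 78 measured; -0.18 when scaled by total counts), below every random list, and replication-dependent histones (-0.24; percentile 0.02), whose near-identical copies make single members uncertain. Cholesterol and fatty acid synthesis genes stood at -0.27 (percentile 0.18), with the desaturase gene SCD at -0.77 and SREBF2 at -0.80. Mitochondrially encoded genes stood at -0.31 (percentile 0.84), actin cytoskeleton and adhesion genes at -0.18 (-0.46 to 0.09; percentile 1.78; 6 of 34 at least 1.5-fold lower), with ITGB4 at -1.47, ACTN4 at -1.04 and ITGB5 at -1.39 but ITGB1 at 0.67, and the 5 measured enterocyte and colonocyte markers at -0.58 (percentile 1.08), with VIL1 at -0.84.

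The other lists measured in mRNA lay between percentiles 2.5 and 97.5. Their medians were -0.03 for let-7 targets, -0.02 for the IMP family, LIN28 and let-7 pathway, -0.16 for mRNAs described as IMP1 targets, 0.17 for the Notch pathway, -0.01 for YAP and TEAD targets, 0.15 for ERK feedback genes and 0.07 for insulin and IGF signalling. They were -0.05 for epithelial adhesion, -0.10 for mesenchymal genes, -0.18 for translation factors, 0.01 for ribosome biogenesis, -0.02 for mitochondrial ribosomal proteins and -0.06 for nuclear-encoded oxidative phosphorylation. Glycolysis stood at -0.21, hypoxia response at -0.19, heat shock proteins at -0.08, oxidative stress genes at -0.13, G1/S and DNA replication at -0.12, interferon-stimulated genes at -0.04, NF-kappaB genes at -0.10, the proteasome at 0.04 and autophagy and lysosome at 0.08. The adhesion list hid opposite members: KRT8 (-1.22), KRT18 (-1.10) and KRT19 (-0.81), keratins of simple epithelia, were lower, and CDH1 (0.89), which encodes E-cadherin, was higher. Markers of other cell types were sparse: 2 haematopoietic markers (CD68 and GZMB), 2 fibroblast, endothelial and muscle markers (KDR and DES), 2 neural and germ cell markers (TUBB3 and NES) and 1 secretory lineage marker (DCLK1) passed the filter.

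**Figure D2:**
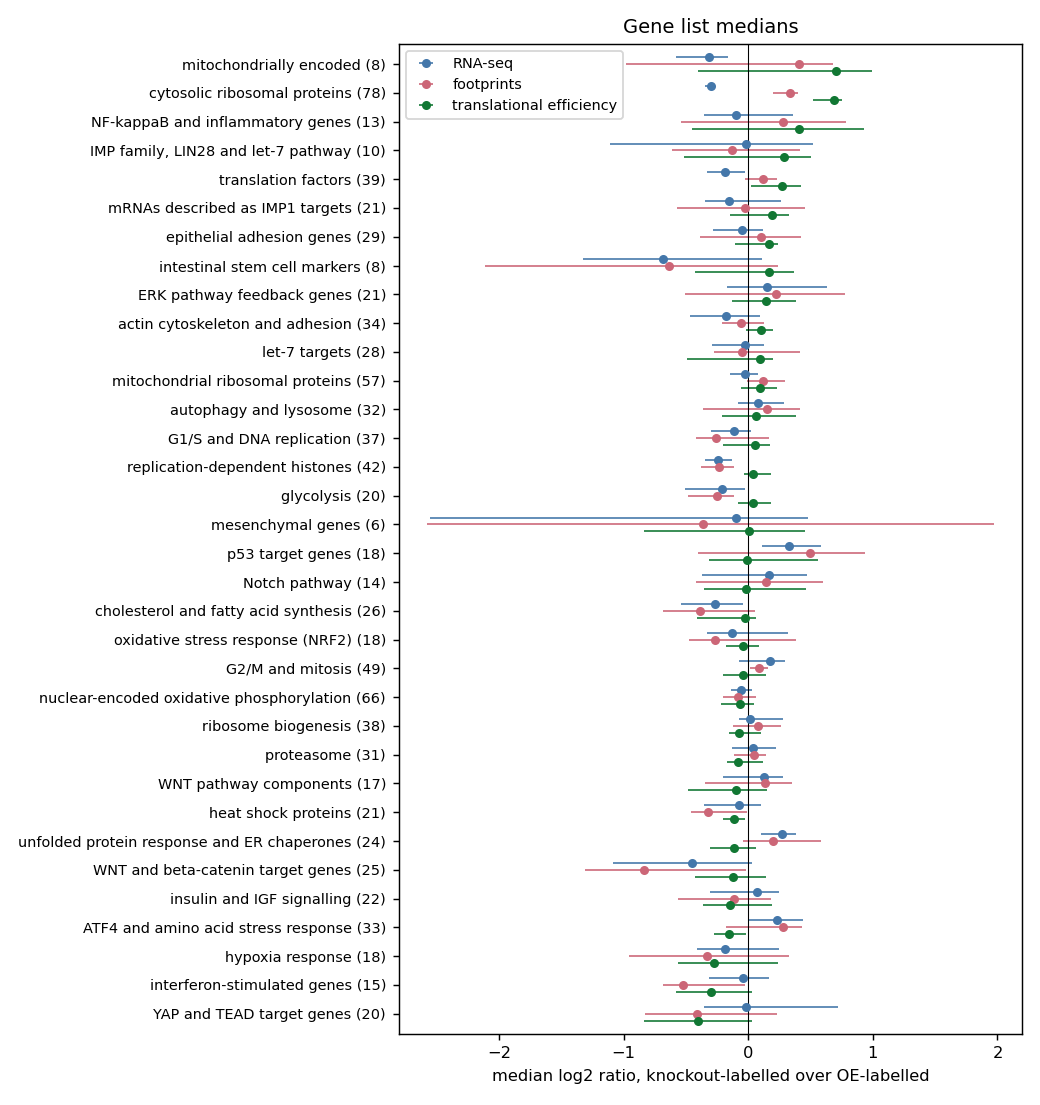
Median log2 ratio (knockout-labelled over OE-labelled) of each gene list with at least 5 measured members in all 3 ratios, for RNA-seq, footprints and translational efficiency; bars are order-statistic 95% intervals over members, and the number measured for translational efficiency is in parentheses. Cytosolic ribosomal proteins have medians of -0.30 in RNA-seq, 0.33 in footprints and 0.69 in translational efficiency.

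In ribosome footprints, 341 of 7323 genes were at least 2-fold higher and 325 at least 2-fold lower in the knockout-labelled library, against 0.33 past 2-fold from counting noise alone. FLNC was 6.32-fold higher (259 against 1986 counts) and DPEP1 5.95-fold. DCP2, which encodes an mRNA decapping enzyme, was 5.31-fold higher, CTH, an enzyme of cysteine synthesis, 5.03-fold, the lipase gene MGLL 4.87-fold, the EGF receptor ligand gene HBEGF 4.73-fold and IFT122 4.53-fold. The cytokine gene IL11 was 3.98-fold higher, GTPBP2 3.66-fold, CYR61 3.36-fold and GADD45A 3.14-fold. IGHE went from 0 to 110 counts, 30.3-fold higher against a floor of 3 counts, with the uncertainty given above. Its interval reached down to a log2 ratio of 4.60, nearer to 0 than that fold. At the other end, IGFBP3 had 204 and 0 footprint counts (82.4-fold lower against the floor). The protease inhibitor gene CST5 had 130 and 0 (52.5-fold lower against the floor). Their intervals reached log2 ratios of -6.05 and -5.395, also nearer to 0 than these folds. REC114 had 114 and 0 (46.0-fold lower against the floor) with 0 RNA counts in both lines. Few counts also remained for APCDD1 (104 against 2; log2 ratio -5.66, -9.04 to -4.09), the kinase gene ZAP70 (139 against 3; -5.59, -8.11 to -4.23) and ASB4 (106 against 3; -5.20, -7.72 to -3.83). IQGAP2 was 9.42-fold lower, LINGO1 7.44-fold, S100A3 6.80-fold, TGFBI 5.96-fold, EPAS1 5.70-fold and NSMF 5.45-fold.

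The same direction past 2-fold in both assays was found for 62 genes higher and 92 lower among 7260 genes measured in both, against 6.72 and 7.99 for independent lists. Besides FLNC and DPEP1, those furthest above 0 in both included TNC (3.43-fold in mRNA and 3.05-fold in footprints), DYSF (2.89-fold and 3.17-fold), LIMA1 (2.91-fold and 2.90-fold), JUN (2.52-fold and 2.61-fold) and TXNIP, an inhibitor of thioredoxin (3.14-fold and 2.46-fold). Those furthest below included LIN28B and NELL2 (4.12-fold lower in mRNA and 3.77-fold in footprints). CAB39L was lower in mRNA and higher in footprints, and RPGR was higher in mRNA and lower in footprints; no other gene passed 2-fold in opposite directions. Across genes, which are not independent replicates, the log2 ratios of the assays had a Pearson r of 0.51 and a Spearman rho of 0.41.

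**Figure D3:**
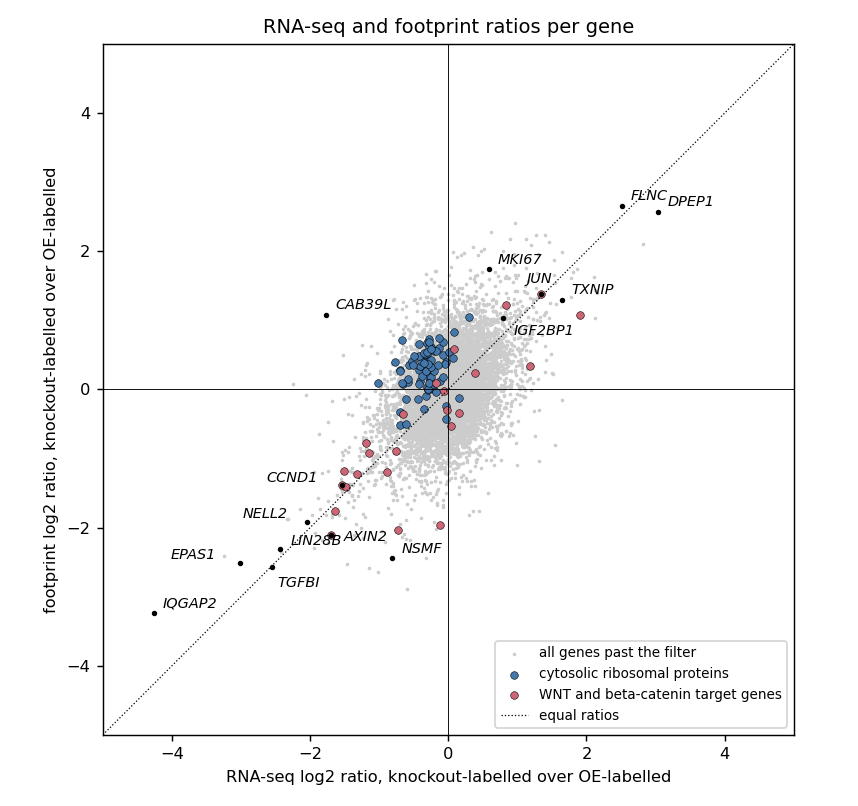
Footprint against RNA-seq log2 ratio (knockout-labelled over OE-labelled) for the 7260 genes measured in both assays, with cytosolic ribosomal proteins in blue and WNT and beta-catenin targets in red; IGHE, APCDD1, ASB4 and IGFBP3 lie outside the axes. Most ribosomal protein genes sit left of 0 and above 0, and AXIN2 and CCND1 sit in the lower left with log2 ratios of -1.69 and -1.53 in RNA-seq.

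Footprints of WNT and beta-catenin targets were lower too, with a median of -0.84 (-1.31 to -0.02; 26 measured; 14 at least 1.5-fold lower and 4 higher), below every random list. Without the 5 lowest members the median was -0.36. AXIN2 stood at -2.11, PROX1 at -2.04, WNT6 at -1.76, SP5 at -1.41, CCND1 at -1.39, RNF43 at -1.23, NOTUM at -1.20 and CD44 at -1.18, against 1.39 for JUN, 1.23 for FOSL1 and 1.07 for CCDC80. Stem cell markers, which share AXIN2, RNF43 and CD44 with the WNT list, had a median of -0.64 (-2.11 to 0.24, 8 measured, percentile 0.20). YAP and TEAD targets had a footprint median of -0.41 (-0.83 to 0.23; percentile 0.07; 9 of 20 at least 1.5-fold lower and 4 higher), with ANKRD1 at -1.81 and the receptor kinase gene AXL at -0.77 but CYR61 at 1.75 and GADD45A at 1.65. Interferon-stimulated genes stood at -0.52 (percentile 0.03), including IFITM1 (-0.95) and IFITM3 (-0.79), cholesterol and fatty acid synthesis at -0.39 (-0.69 to 0.06; percentile 0.09; SCD -1.46, against EBP at 0.63), and heat shock proteins at -0.32 (percentile 0.08; HSPA8 -0.61). Also below percentile 2.5 were histones (-0.24), glycolysis (-0.25; LDHA -0.65 and SLC2A3 -0.96), the hypoxia response (-0.33, -0.96 to 0.33; EGLN3 -1.03, against CA9 at 1.04), oxidative stress genes (-0.26, -0.47 to 0.38) and G1/S and DNA replication (-0.26, -0.42 to 0.17; MCM7 -0.72 and TYMS -1.03, against RFC5 at 0.76). Against random lists not matched on count, glycolysis (percentile 3.11) and oxidative stress genes (percentile 3.41) did not stay below 2.5. Above percentile 97.5 were the cytosolic ribosomal proteins (0.33, 0.20 to 0.40; 12 at least 1.5-fold higher, 0 lower), higher than every random list, p53 targets (0.49, -0.40 to 0.94; CDKN1A 1.24, against DDB2 at -0.55) and ATF4 and amino acid stress genes (0.28, -0.17 to 0.43; DDIT3 1.55 and ATF4 itself 0.63, against XPOT at -0.76). The intervals of both cross 0. The mitotic genes had a footprint median of 0.08 (percentile 83.0; 6 at least 1.5-fold higher and 6 lower), with the proliferation marker MKI67 at 1.74.

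Among mRNAs described as IMP1 targets, which the labels would place at the centre of the comparison, the medians were -0.16 in mRNA (percentile 7.47) and -0.03 in footprints (percentile 28.0). CCND1 and CD44, given above, were the lowest members. CTNNB1, which encodes beta-catenin, stood at -0.35 in mRNA and -0.34 in footprints, ACTB at -0.18 and -0.28, EGFR at -0.43 and -0.57, and ITGA6 at -0.45 and -0.71. IGF2 stood at -0.15 and 0.08, and BTRC at 0.16 and 0.49. The drug efflux transporter gene ABCB1 stood at 0.68 and 1.49, and CDH1 at 0.89 and 1.11. Let-7 targets had a footprint median of -0.05 (percentile 27.7), with HMGA2 at -0.72 in mRNA and -1.26 in footprints, ARID3B at 0.19 and 1.00, and NRAS at -0.19 and 0.69.

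Translational efficiency, the footprint ratio over the mRNA ratio, was at least 2-fold higher for 265 of 7260 genes and at least 2-fold lower for 261, against 3.14 from counting noise alone. It was highest for CAB39L (7.23-fold; log2 ratio 2.85, 2.21 to 3.50), the inflammasome adaptor gene PYCARD (5.03-fold), TMEM94 (4.30-fold), FOXRED1, an assembly factor of respiratory complex I (4.27-fold), NELFA (4.08-fold), BNIP1 (4.02-fold), TPD52L1 (3.99-fold), TFPT (3.79-fold), CDK5 (3.72-fold), SCAMP3 (3.56-fold) and TOR1B (3.48-fold). The genes lowest by the interval bound nearest to 0 included, in no order, LINGO1 (4.89-fold lower; log2 ratio -2.29, -2.88 to -1.70), SELO (5.11-fold), RPGR (5.06-fold), the ERK pathway inhibitor gene SPRED2 (4.58-fold), ALDH8A1 (4.35-fold), SAMD1 (4.33-fold), FAM57A (4.32-fold), MFAP3 (4.25-fold), the transcription factor gene RFX5 (4.23-fold) and NSMF (3.10-fold, from 17160 and 13294 RNA counts). APCDD1 stood at -3.32 (-5.15 to -1.48), with 2 footprint counts in the knockout-labelled library. Because the mRNA ratio is the divisor, chance error in it moves efficiency the opposite way. With total counts the median of all genes moved to -0.10 and the split to 194 higher and 358 lower (195 and 355 without mitochondrially encoded genes in the totals).

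Cytosolic ribosomal proteins, the structural proteins of the ribosome, had a median efficiency ratio of 0.69 (0.52 to 0.75; 78 measured), above every random list. 42 were at least 1.5-fold higher and 0 at least 1.5-fold lower. RPS4X stood at 0.69 (0.64 to 0.75), RPS7 at 0.87 and RPS27A at 0.83, and many ribosomal protein genes have processed pseudogenes that can share their reads. Translation factors had a median of 0.28 (0.02 to 0.42; percentile 99.9; 8 of 39 at least 1.5-fold higher), with the elongation factor genes EEF1A1 at 0.81 and EEF2 at 0.75 and the initiation factor gene EIF4B at 0.75. The 8 measured mitochondrially encoded genes had a median of 0.71 (-0.40 to 0.99; percentile 99.9), with MT-CO1 at 0.83 and MT-CO2 at 0.68. NF-kappaB genes stood at 0.41 (-0.45 to 0.93; 13 measured; percentile 99.01), with IL32 at 0.99, SOD2 at 0.93 and NFKBIA at 0.72 but TNFAIP2 at -0.67, NFKB2 at -0.62 and NFKB1 at -0.45. YAP and TEAD targets stood at -0.40 (-0.83 to 0.03; percentile 0.07; TEAD1 -0.87, against GADD45A at 0.65), the hypoxia response at -0.27 (-0.56 to 0.24; percentile 1.16; P4HA2 -0.76, against HK2 at 0.53 and DDIT4 at 0.53) and ATF4 and amino acid stress genes at -0.15 (percentile 0.16; XPOT -0.88), with ATF4 itself at 0.84. Against random lists not matched on count, the hypoxia response (percentile 2.70) and the ATF4 list (percentile 7.77) no longer stood apart in efficiency. WNT and beta-catenin targets (-0.12), p53 targets (-0.01), ribosome biogenesis (-0.07), mitochondrial ribosomal proteins (0.09), nuclear-encoded oxidative phosphorylation (-0.07), IMP1 targets (0.19) and let-7 targets (0.10) lay between percentiles 2.5 and 97.5.

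Within each line, footprint counts over RNA counts were centred on the median gene. Cytosolic ribosomal proteins lay below that gene in the OE-labelled line (median log2 -0.20, -0.42 to -0.05) and above it in the knockout-labelled line (0.44, 0.26 to 0.59). Their position depends on the centring: with genes of a mean count of at least 200 as the reference, the medians were -0.52 and 0.10. Histones had the highest medians in both lines (1.29 and 1.37), ahead of heat shock proteins (0.92 and 0.80) and the proteasome (0.89 and 0.74). Mitochondrially encoded genes (8 measured) had the lowest (-4.33 and -3.64), followed by insulin and IGF signalling (-1.03 and -1.16). All mitochondrially encoded genes together held 0.0787% and 0.109% of footprint counts in the OE-labelled and knockout-labelled lines, against 1.31% and 1.14% of RNA counts. How well footprints of mitochondrial ribosomes were captured was not tested, so their median may reflect the assay. Let-7 targets stood at -0.70 and -0.69. Since the counted part of the transcript is not given, differences between lists within a line cannot be read as translation alone. Across 7260 genes the efficiencies of the lines had a Pearson r of 0.84.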

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

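The test on coding length below was chosen after the ribosomal protein result was seen. Cytosolic ribosomal protein genes moved in opposite directions in the assays, with a median log2 ratio of -0.30 in mRNA and 0.33 in footprints of the knockout-labelled over the OE-labelled libraries. The median of their per-gene efficiency ratios was 0.69. Scaled by total counts, the mRNA median was -0.18, so its distance from 0 depends on the scaling. That scaling moved all genes alike, with the mRNA median of all genes going from 0.01 to 0.13. The difference between the assays was not tested, since each has 1 library per line.

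The tables argue against 3 technical explanations as the whole cause. After the median of genes of like coding length (10 bins) was subtracted, the list median was 0.61 (0.41 to 0.65). This argues against a trend across those bins as the whole cause. Length differences inside a bin were not removed. Other genes as abundant in footprints (166 genes) had a median of -0.0157 (-0.07 to 0.04). They spanned the lower to the upper quartile of ribosomal protein abundance, and other lists of the translation machinery were left out. This argues against a trend with abundance shared by genes outside that machinery in that range. Translation factors had a median of 0.28. The 21 ribosomal protein genes with at most 3 annotated processed pseudogenes had a median of 0.52 (0.31 to 0.82), which argues against reads shared with pseudogenes. A difference in footprint digestion or size selection between 2 single libraries stays open, as does a difference between the lines themselves, and neither was tested.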

How the results depend on the processing

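No paired analysis was possible because each line has 1 library per assay, and leaving out a replicate was not possible for the same reason. The counts of genes past 2-fold (639 in mRNA, 666 in footprints, 526 in translational efficiency) stayed within 1.5 times under the 4 other scalings and with 5 added to each count. They changed with the filter and the threshold, which set the genes that can be counted. With a mean count of at least 10 they were 1463, 1908 and 1777; of at least 200, 181, 131 and 41; with no filter, 3933, 4007 and 3581; at 1.5-fold, 2074, 2125 and 1911; and at 3-fold, 127, 135 and 77. Of the 526 efficiency calls, 41 remained at a minimum of 200, so most were of genes with lower counts in 1 or both assays. In mRNA, 181 of 639 remained. The number of genes compared at each other minimum is not given here. The correlation of the mRNA and footprint ratios was 0.62 with a mean count of at least 200 and 0.41 by rank. IGF2BP1 and LIN28B kept their directions under all 4 other scalings. This was a weak check, because those scalings shifted all genes by little against the ratios of these genes. The median of all genes stayed between -0.01 and 0.13 in mRNA and between 0.02 and 0.05 in footprints.

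Over 103 list medians and 720 settings, 694 stayed within the median's interval, 26 left it and 0 reversed. Staying inside was a weak check, because these intervals over members are often wide, such as -1.08 to 0.03 for WNT targets in mRNA. Total counts moved the mRNA median of all genes only from 0.01 to 0.13. The ribosomal protein mRNA median moved to -0.18 with total counts and to -0.19 without mitochondrially encoded genes in the totals, a setting chosen for lists after the data were seen. Centred on genes with a mean count of at least 200, the efficiency of ribosomal proteins was -0.52 in the OE-labelled and 0.10 in the knockout-labelled line. Of 3760 single-gene settings, 3557 stayed within the counting interval, 199 left it and 4 reversed, all under total counts: LDHB mRNA to 0.0026 and, without mitochondrially encoded genes, 0.0001, and HSPD1 mRNA to 0.0450 and 0.0425. These reversals follow from a shift shared by all mRNA ratios, since total counts moved the median of all genes from 0.01 to 0.13. In settings chosen after the data were seen, the WNT target median in mRNA was -0.29 once the median of each member's 40 nearest genes was subtracted, -0.14 without its 5 lowest and -0.66 without its 5 highest members (footprints -0.85, -0.36 and -1.18). Of 103 list percentiles, 33 lay outside 2.5 to 97.5 with matched random lists, 30 with unmatched ones and 29 with both. Glycolysis and oxidative stress genes in footprints and the hypoxia response and ATF4 lists in efficiency were outside only with matched lists, and translation factors in mRNA (percentile 0.96) only with unmatched ones. Depth limits single genes: LEF1, with 57 and 15 footprint counts, did not reach the filter.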

Other observations

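The tests of a label swap and of a whole-chromosome difference below were chosen after the patterns were seen. Genes of chromosome 21 were lower together in the knockout-labelled libraries, with a median log2 ratio of -0.53 in mRNA (-0.65 to -0.43; 105 genes) and -0.44 in footprints (-0.67 to -0.27; 79 genes), below every matched random list. Members included MRPS6, a mitochondrial ribosomal protein gene (-1.39 in mRNA and -1.37 in footprints), the ATP synthase genes ATP5O (-0.69 and -1.21) and ATP5J (-0.64 and -0.91), the glycolytic enzyme gene PFKL (-0.50 and -0.98) and LSS, an enzyme gene of sterol synthesis (-0.29 and -1.11). Chromosome 13 was also lower (-0.22 and -0.19), and chromosomes 14 (0.25 and 0.18) and 3 (0.20 and 0.17) were higher. Among 234 windows of 40 neighbouring genes, the lowest mRNA median, -0.59, was on chromosome 4 from 499221 to 6884170 (footprints -0.51), and the highest, 0.40, on chromosome 3 from 126481281 to 133895816 (footprints 0.32). Over these windows the mRNA and footprint medians had a Pearson r of 0.70.

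As a hypothesis, the lines may differ in the copy number of chromosome 21. The medians of both position-ordered parts of the chromosome lay between -0.57 and -0.41 in both assays, and the highest of their upper 95% bounds was -0.19, as a difference along the whole chromosome would give. Subtracting the medians of genes of like GC content and coding length left a median of -0.52 (-0.66 to -0.46), which argues against such a trend. DNA copy number was not measured here, and whether the label or clonal history of the lines goes with it was not tested.

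IGF2BP1, higher in the knockout-labelled libraries, raises the question of the labels. LIN28B was lower there, but both lines are labelled as overexpressing it. Without a library of the parental SW480 line, its level cannot be judged against that label. The 40 measured genes nearest to IGF2BP1 had a median mRNA log2 ratio of -0.19 (-0.48 to -0.03), which argues against a copy number gain of its region, and those nearest to LIN28B had one of 0.0509 (-0.08 to 0.20), which argues against a loss of its region. The latter does not bear on reads of a LIN28B transgene, which the counts do not separate. A swap of the labels of both lines would place IGF2BP1 lower in the true knockout, as its mRNA log2 ratio of 0.79 has it, but that value is the pattern itself. The further condition that IGF2BP1 footprints be near absent in that line was added after the value was seen. The OE-labelled libraries still held 840 RNA and 332 footprint counts of IGF2BP1. Such counts do not show whether intact IMP1 was made, so this condition cannot decide. A swap cannot be told apart from a line-to-line difference in expression. Reads from a knockout allele with a small frameshift would still be counted, and no read positions were used here.

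A few genes took large and assay-specific shares of the counts. PLCG2 held 3.94% and 3.74% of RNA counts in the OE-labelled and knockout-labelled libraries but 0.128% and 0.0798% of footprint counts. LSM4 held 0.0283% and 0.0232% of RNA counts but 1.28% and 0.627% of footprint counts. The MTRNR2L genes, nuclear copies of mitochondrial ribosomal RNA sequence, together held 12.03% and 8.54% of RNA counts and 2.91% and 2.13% of footprint counts. Their reads cannot be separated with certainty from those of mitochondrial ribosomal RNA itself. These counts stayed in the totals from which mitochondrially encoded genes were left out.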
